A study of Mus musculus with 4 samples.

How the data were processed

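The series measured gene expression in single brain cells of C57BL6 mice sorted for CD31 by flow cytometry, after removal of meninges, cerebellum and olfactory bulbs, with droplet libraries of the 10x Genomics 3 prime v3.1 chemistry. Per the labels, mice ate a control diet or a diet with PLX5622 at 1200 ppm for 1 month, and each diet has 2 libraries made from 3 mice. The deposited matrices hold raw UMI counts per gene and barcode, per the file headers and the whole-number values, for every barcode with at least 1 count and without cell calling. Per the submitters' processing notes, Cell Ranger 6.0.1 and Seurat 4.0 were used and the builds mm10 and mm39 are named with no role, while the file headers name another Cell Ranger version. Which build and annotation gave the counts is not given in the sources used here. The 4 libraries held 567554, 872190, 588657 and 724756 barcodes and 11186648, 38600208, 19044018 and 26949278 UMIs for control diet 1 and 2 and PLX5622 diet 1 and 2. Of 32285 gene identifiers, 32235 were found in GENCODE M21 (GRCm38), which supplied coordinates only. All columns of the files were used.

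Cells were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs, which left 1693, 5509, 3987 and 3670 cells. Their median number of genes was 2153, 2210, 1711 and 2275, and their median mitochondrial share 3.00%, 3.31%, 3.26% and 3.47%. The scrublet doublet caller marked 5 cells (0.0336%), so it has not worked and droplets with more than 1 cell remain among the kept cells. In an alternative chosen after seeing the data, the 499 cells with the highest doublet scores were left out. Counts of all cells were clustered with scanpy 1.11.5 (Python 3.11.15, igraph 0.11.9, scikit-learn 1.9.0), using 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5. Clusters of at least 50 cells outside the endothelial-like class were clustered again with 1500 variable genes, 20 components and 10 neighbours. Endothelial-like cells were clustered again with 2000 variable genes, 20 components and 15 neighbours. Interferon, immediate early, heat shock, hypoxia, mitochondrial, sterol, LXR, fatty acid, MHC class I and cell cycle genes were kept out of that second step for endothelial-like cells. This was done so that a response to the diet did not define the subtypes. Inflammatory genes were not kept out.

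Clusters were named from markers fixed before the data were examined, with at least 3 markers detected, a fold of 4 and detection in 25% of cells for classes other than endothelial, and a fold of 1.2 for endothelial subtypes. These thresholds were set after seeing the clusters but before any diet test. The clustering was repeated once after diet calls had been seen, with the same rules, to make it independent of the processor, and the repeat is the one reported. Names end in "-like" because they rest on markers alone. The markers of the venous clusters include Lcn2, Ackr1, Vcam1, Icam1 and Il1r1, and those of the capillary clusters include Mfsd2a and Rgcc, so these genes are not results within or between subtypes. Free RNA was estimated from barcodes under 100 UMIs and made up 0.190%, 0.519%, 0.430% and 0.465% of the endothelial sums.

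Counts were summed per library and class, since cells are not replicates, and classes with at least 20 cells in each library were tested. Endothelial-like cells, the arterial-like, capillary-like and venous-like subtypes, and smooth muscle-like, pericyte-like and erythroid-like cells met this. Astrocyte-like cells (14, 40, 10 and 21), fibroblast-like cells (2, 10, 5 and 2) and ependymal-like cells (0, 6, 2 and 2) were too few. The test was edgeR 4.0.16 quasi-likelihood (R 4.3.3) with TMM normalization, its default low-count filter, robust estimation and Benjamini-Hochberg adjustment, two-sided at 0.05. The interaction of subtype and diet was tested in 1 model over 12 sums with the library as a block, so that differences are taken within a library, and what remains in a library's sums is treated as independent. Gene lists were fixed before the data were examined. Of 28, the 27 with at least 4 tested members went through camera with a preset correlation of 0.01, camera with an estimated correlation, and fry (limma 3.58.1). Fry tests whether a list's genes move on balance in 1 direction and does not compare them with other genes. DESeq2 1.42.0 and limma-voom served as other tools.

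The genes named in the text came from a rule fixed before the data were examined. It took the 12 higher and 12 lower genes with the largest change among those with an adjusted p under 0.05, a mean of at least 20 CPM and both PLX5622 libraries on the same side of both controls. Up to 4 members of each list with the smallest p and a fixed set of sterol, barrier, adhesion and microglial genes were added. Subtypes and other classes took 5 in each direction and each interaction term the 5 with the smallest p. Members completing a list's count (Csf1, Cxcl10, Tnfaip2, Usp18), the markers of other cell types, and the genes near 0 counts (Col13a1, Fam167b, Grem1, Ttr) were named after their values were seen. Results for some genes that the rule takes are not reported here. Genes with near-identical copies share reads, so Hspa1a and Hspa1b, Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, and Abcb1a and Abcb1b are uncertain, as is Aldoa, which has 2 identifiers.

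A gene at 0 counts in both libraries of a diet was compared with a limit of 3 counts over that diet, a lower bound for counting error only, and shares of 0 were given the 3-count limit. These fold limits and the counting intervals take each UMI as independent. For genes whose UMIs lie in few cells they overstate the certainty. Pairs of libraries were compared by chi-square over genes. Tests were checked on simulated counts with 200 changed genes. For endothelial cells (12626 genes) 61.2%, 85.9% and 98.5% of genes changed by 1.5, 2 and 4-fold were recovered and 7.51% of 173 calls were false. For venous-like cells the recovered shares were 34.3%, 83.3% and 97.0% with 7.19% false, for smooth muscle-like cells 3.23%, 32.8% and 95.0% with 10.1% false, and for the arterial interaction 28.4%, 56.7% and 95.5% with 3.23% false. The false shares lie above 5% in all of these but the interaction.

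Alternatives fixed before the data were examined were a replicate block, each library left out, other normalizations, filters and tools, other limits on cells, subtraction of free RNA, thinning to the smallest library, equal weight to the subtypes, and clustering at resolution 1.0. Chosen after seeing the data were another clustering seed, the removal of high doublet scores, the removal of fenestrated-like cells, and the block, left-out libraries and other tools for the other cell classes. The same replicate number is carried by libraries of both diets, but nothing in the labels ties such libraries to a shared mouse, batch or day, so the tests were unpaired. Clusters outside the endothelial class that stayed unnamed after both steps, and those mixing endothelial with pericyte or erythroid genes, were left out. An endothelial cluster that matched no subtype stayed in the endothelial sums but entered no subtype, equal-weight or interaction fit.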

Results

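Single-cell RNA sequencing was carried out on mouse brain cells sorted for CD31, a surface protein of endothelial cells. C57BL6 mice ate a control diet or a diet containing PLX5622 at 1200 ppm for 1 month. PLX5622 inhibits CSF1R, the receptor on which microglia depend for survival, and the series asked how the loss of microglia affects the brain vasculature. Each diet had 2 libraries made from 3 mice, so a library need not be 1 animal, and the 2 libraries of a diet may share mice. The p-values measure the spread between libraries, part or all of which may be technical, and need not measure the spread between mice. The libraries held 11186648 and 38600208 UMIs (unique molecules counted per gene and cell) on control diet and 19044018 and 26949278 on PLX5622. In the same order, 1693, 5509, 3987 and 3670 cells passed the filters, with medians of 5180, 5573, 3834 and 5921.5 UMIs per cell. Endothelial-like cells made up 13103 of the 14859 kept cells (1513, 4905, 3504 and 3181 per library). No pair of libraries agreed within sampling noise, as copies of 1 library would. Chi-square per degree of freedom was 9.70 between the control libraries, 6.02 between the PLX5622 libraries and 9.49 to 15.3 between libraries of different diets.

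Microglial transcripts were examined first, since they check the diet labels. Csf1r, the drug's target receptor, stood at 22.6 and 1.48 CPM (counts-per-million) over all barcodes of control diet 1 and 2, against 0.0525 and 0.186 CPM in PLX5622 diet 1 and 2. Cx3cr1, the fractalkine receptor of microglia, read 22.6, 1.503, 0.0525 and 0.0742 CPM in the same order. The complement genes C1qa, C1qb and C1qc had 240, 267 and 247 UMIs in control diet 1, 99, 83 and 79 UMIs in control diet 2, and 0 in both PLX5622 libraries. P2ry12, the purinergic receptor of microglia, read 13.7 and 1.53 CPM on control diet and 0.210 and 0.371 CPM on PLX5622. Control diet 1 held several times the level of control diet 2 for each of these genes. At least 4 of 12 microglial markers were detected in 2 and 1 kept cells of control diet 1 and 2 and in 0 cells of either PLX5622 library, which allows shares of up to 0.0752% and 0.0817%. The CD31 sort selects against microglia in both diets, so these shares do not measure depletion in the tissue.

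**Figure D1:**
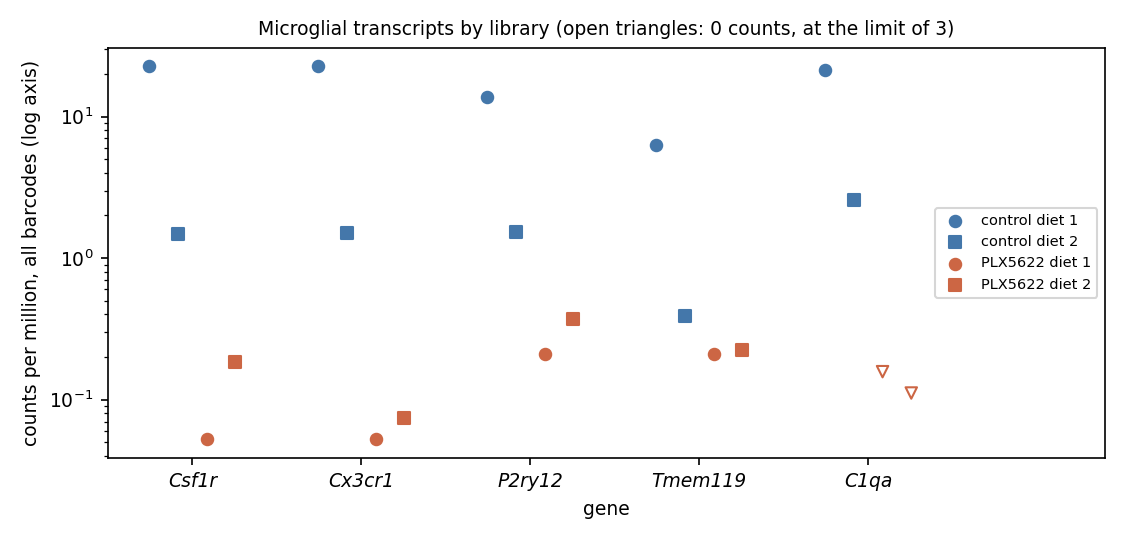
CPM of 5 microglial markers over all barcodes of each library, on a log axis. Circles and squares are libraries 1 and 2 of each diet, and open triangles mark 0 counts drawn at the 3-count limit. Csf1r is at 22.6 and 1.48 CPM on control diet and at 0.0525 and 0.186 CPM on PLX5622.

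Brain endothelial cells on PLX5622 carried more transcripts of the cholesterol synthesis pathway. Idi1, which encodes an isomerase of isoprenoid assembly, rose from 21.9 ± 1.14 to 60.9 ± 0.201 CPM (SD, n = 2 per diet), a log2 fold change of 1.46 ± 0.10 (SE) with an adjusted p of 1.2e-06. Sqle, which encodes squalene epoxidase, rose by 1.97 ± 0.15 on the log2 scale and Msmo1, a sterol demethylation enzyme, by 1.52 ± 0.11. Abca1, the cholesterol exporter, fell from 48.7 ± 10.0 to 21.3 ± 0.818 CPM, a log2 fold change of -1.17 ± 0.13. Among 12773 genes tested, 106 were higher and 50 lower on PLX5622 at an adjusted p under 0.05 in edgeR's quasi-likelihood test, so 67.9% of the changed genes were higher. On library totals without normalization factors, 90 were higher and 67 lower (57.3% higher). With control diet 1 left out the counts were 51 and 38, with 64 of the 156 genes shared, and without control diet 2 they were 45 and 19, with 51 shared.

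Of the 20 tested genes of cholesterol synthesis, 14 rose, 0 fell and 6 did not pass, and 17 rose when adjusted over the list alone. The enzymes that rose ranged from Hmgcs1, which makes the first committed precursor of the pathway (1.03 ± 0.10 on the log2 scale), through Fdps, which makes farnesyl diphosphate (1.22 ± 0.12), to Cyp51, the lanosterol demethylase (1.42 ± 0.10). The list's median was 0.86, and camera placed it higher than other genes (adjusted p = 2.6e-83 with a preset correlation, adjusted p = 0.109 with an estimated correlation). Without control diet 2 the number of members that rose was 9, and in DESeq2 it was 13, without Acat2 (adjusted p = 0.238). Of the 8 tested genes of sterol uptake and sterol feedback, 5 rose, 0 fell and 3 did not pass, with 5 when adjusted over the list alone (adjusted p = 0.109 with an estimated correlation). They included Insig1, the sterol-sensing retention protein (1.46 ± 0.10), Srebf2, the transcription factor that drives the pathway (0.72 ± 0.09), and Tmem97, a sterol-binding membrane protein (0.99 ± 0.15, adjusted p = 0.0818 without control diet 2). Both lists were fixed before the data were examined but with knowledge of the series title, which names cholesterol metabolism, so they are not independent of the study's own subject. In the GENCODE M21 annotation (GRCm38) these are protein-coding genes, with Sqle on chromosome 15 from 59315077 to 59331192, Insig1 on chromosome 5 from 28071363 to 28078662, Idi1 on chromosome 13 from 8885501 to 8892451, and Hmgcs1 on chromosome 13 from 119690379 to 119708260.

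**Figure D2:**
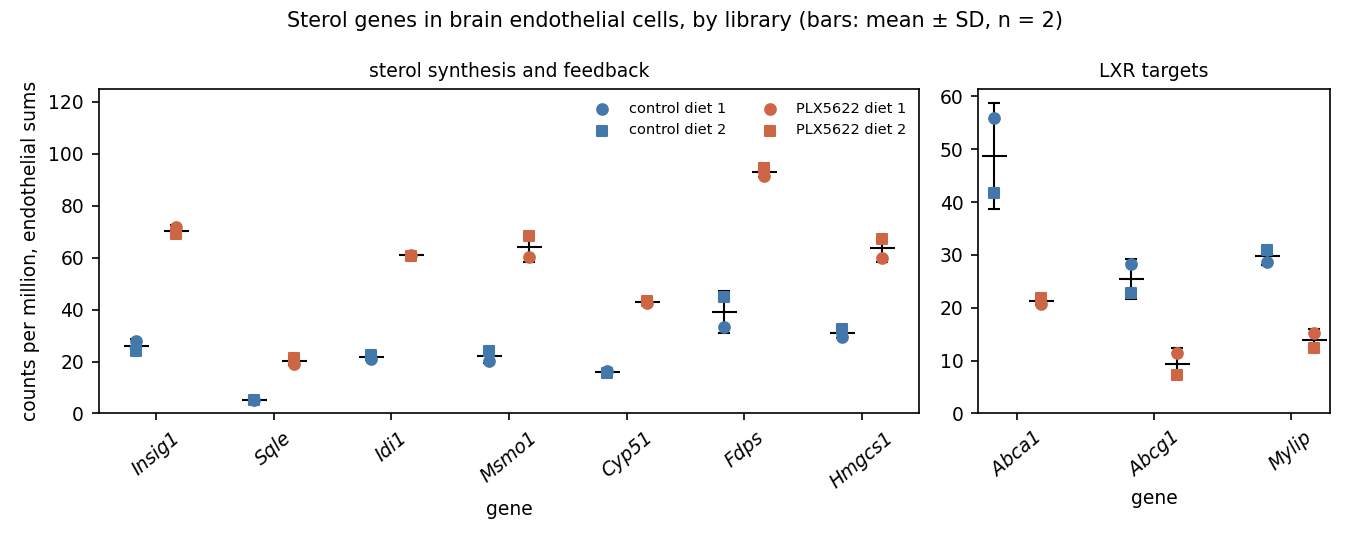
CPM of sterol genes in the endothelial sums of each library (circles and squares, libraries 1 and 2; horizontal bars, mean; whiskers, SD, n = 2). Idi1 reads 21.9 CPM on control diet and 60.9 CPM on PLX5622, and Abca1 reads 48.7 and 21.3 CPM.

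The next list held genes of cholesterol efflux and targets of LXR, the oxysterol receptor that promotes cholesterol export. Of 12 tested, 1 rose, 3 fell and 8 did not pass, with 1 and 3 when adjusted over the list alone (lower by camera, adjusted p = 0.266 with an estimated correlation). The members that fell were Abca1 and Abcg1, both cholesterol exporters, and Mylip, a ubiquitin ligase. Abcg1 fell by 1.44 ± 0.18 and Mylip by 1.12 ± 0.12 on the log2 scale. The member that rose was Ch25h, which makes the oxysterol 25-hydroxycholesterol, by 0.83 ± 0.15, a call lost without control diet 1, control diet 2 or PLX5622 diet 2 (adjusted p of 0.161, 0.137 and 0.0766). Of 13 tested genes of fatty acid synthesis, 2 rose, 1 fell and 10 did not pass, with 7 and 1 when adjusted over the list alone (higher by camera, adjusted p = 0.266 with an estimated correlation). Fasn, the fatty acid synthase, rose by 1.33 ± 0.17 and Fads1, a fatty acid desaturase, by 0.73 ± 0.12, while Scd1, the stearoyl-CoA desaturase, fell by 2.21 ± 0.38. Without control diet 2 none of these passed (Fasn 0.082, Fads1 0.109, Scd1 0.207 as adjusted p), leaving 0 of the list, and Scd1 also missed the threshold with equal weight to the subtypes (adjusted p = 0.0667). Abca1 lies on chromosome 4 from 53030787 to 53159895 and Mylip on chromosome 13 from 45389742 to 45412022.

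Lcn2, an iron-carrier-binding acute phase protein, rose from 1.95 ± 1.04 to 34.3 ± 7.60 CPM (log2 fold change 3.91 ± 0.24, adjusted p = 1.4e-05). Ptgs2, the inducible cyclooxygenase, rose from 11.5 ± 2.62 to 35.5 ± 2.54 CPM and Cxcl1, a neutrophil chemokine, from 33.2 ± 6.46 to 58.8 ± 5.86 CPM. Of 13 tested genes of inflammatory signalling, 6 rose (also Il1r1, Csf1 and Cxcl10), 1 fell (Tnfaip2) and 6 did not pass, with 8 and 1 when adjusted over the list alone (adjusted p = 0.109 with an estimated correlation). The counts were 3 and 0 without control diet 1, as they were without control diet 2. Tnfaip2 (adjusted p of 0.369 and 0.0588) and Cxcl10 (0.343 and 0.0531) did not pass in DESeq2 or limma-voom, both of which passed Lrg1 as higher. Il1r1, the interleukin-1 receptor, rose by 0.67 ± 0.11 but had an adjusted p of 0.0682 and 0.0584 without control diet 1 and 2. Of 7 tested genes of leukocyte adhesion, 2 rose (Ackr1 and Sele), 0 fell and 5 did not pass, with 2 when adjusted over the list alone (adjusted p = 0.129 with an estimated correlation). Ackr1, the chemokine-binding receptor of venules, rose from 0.95 ± 0.873 to 15.3 ± 5.03 CPM, and did not pass when mitochondrial UMIs were limited to 5% (adjusted p = 0.359) or with no filter on low counts (adjusted p = 0.0869). Sele, which encodes E-selectin, had 1 UMI on control diet and 68 on PLX5622, a ratio of 75.8 with a counting interval from 13.2 to 3039, and did not pass without control diet 2 (adjusted p = 0.118). The adhesion receptors Vcam1 (1.18 ± 0.51, adjusted p = 0.611) and Icam1 (0.44 ± 0.17, adjusted p = 0.382) did not pass in edgeR or DESeq2, but limma-voom passed Vcam1 (adjusted p = 0.0368). Leaving out control diet 2 gave 1 adhesion gene and leaving out PLX5622 diet 1 gave 4. Lcn2 lies on chromosome 2 from 32384633 to 32388252, Ptgs2 on chromosome 1 from 150100031 to 150108227 and Ackr1 on chromosome 1 from 173331886 to 173333750.

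Of 20 tested interferon-response genes, 5 rose, 0 fell and 15 did not pass, with 14 when adjusted over the list alone (higher by camera, adjusted p = 0.266 with an estimated correlation). The 5 were Isg15, a ubiquitin-like protein (0.70 ± 0.13), Ifi44 (0.52 ± 0.10), Ifit1, an RNA-binding antiviral protein (0.50 ± 0.10), Bst2, which tethers viruses (0.55 ± 0.12), and Usp18, which removes Isg15 from proteins (0.46 ± 0.10). The number was 0 without control diet 1, 2 without PLX5622 diet 2 and 11 without PLX5622 diet 1. The adjusted p of Isg15 was 0.131 without control diet 1 and 0.054 without PLX5622 diet 2, that of Ifit1 0.129, 0.0625 and 0.305 without control diet 1, control diet 2 and PLX5622 diet 2, that of Bst2 0.168 and 0.303 without control diet 1 and PLX5622 diet 2, and that of Ifi44 0.102 without control diet 1. Usp18 did not pass in DESeq2 (adjusted p = 0.0538). Of 13 MHC class I genes 0 passed in edgeR, DESeq2 and limma-voom, with 0 at an unadjusted p under 0.05 in each and 0 when adjusted over the list alone. Leaving out control diet 1 gave 2 higher, and leaving out control diet 2 gave 1 lower.

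Genes of the blood-brain barrier did not pass in any of their lists. Cldn5, the main tight junction protein of brain endothelium, read 7390 ± 987 and 7343 ± 134 CPM (log2 fold change -0.01 ± 0.17, adjusted p = 0.992). Slc2a1, the glucose transporter, read 1685 ± 33.8 and 1786 ± 26.3 CPM, and Abcb1a, the P-glycoprotein efflux pump, 1568 ± 161 and 1559 ± 55.5 CPM. The junction proteins Ocln (-0.11 ± 0.10) and Tjp1 (-0.06 ± 0.11) and the lipid transporter Mfsd2a (0.11 ± 0.12) did not pass either. Among tight and adherens junctions, 0 of 13 tested passed in edgeR, DESeq2 and limma-voom, and 0 had an unadjusted p under 0.05 in any of them. Among blood-brain barrier transporters, 0 of 16 passed in the 3 tools, with 1, 3 and 2 at an unadjusted p under 0.05. Among efflux pumps, 0 of 6 passed, with 0, 1 and 0 at an unadjusted p under 0.05. Adjusted over the list alone, 0 members of each of these 3 lists passed. In simulated data with this comparison's depth and spread, a 1.5-fold change was recovered for 61.2% of genes and a 2-fold change for 85.9%, so changes of these sizes can be missed. Cldn5 lies on chromosome 16 from 18776847 to 18778262.

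The list of transcytosis and permeability genes had 0 of 9 tested members past the threshold in edgeR, 0 when adjusted over the list alone and 1 at an unadjusted p under 0.05. That gene was Plvap, the diaphragm protein of fenestrated capillaries, with 416 UMIs in control endothelial cells and 0 on PLX5622. Control diet 1 and 2 held 41 and 375 of the 416. By UMI counts Plvap was at least 124-fold lower against a limit of 3 counts over the PLX5622 libraries together. DESeq2 and limma-voom passed Plvap, as did edgeR in each of the fits that left out 1 library. Camera called the list lower (adjusted p = 0.0334, and adjusted p = 0.518 with an estimated correlation), its median log2 fold change was -0.03, and its mean was -0.76 with Plvap at its bound. Plvap marked a group of fenestrated-like cells, of which the control libraries had 6 and 13 and the PLX5622 libraries 0, which allows shares of up to 0.0752% and 0.0817% of kept cells. UMIs of the same cell are not independent, so with so few cells the fold limits for Plvap and Esm1 overstate the certainty. Esm1, a proteoglycan of endothelial tip cells that is also among the fenestrated markers, was at least 19.4-fold lower (65 UMIs against 0), and had too few counts to be tested once the fenestrated-like cells were left out. Col13a1, a membrane collagen, was at least 22.4-fold lower (75 against 0), while Fam167b had 73 and 3 UMIs, a ratio of 21.8 with a counting interval from 7.18 to 108. Plpp3, a lipid phosphatase and another marker of that group, fell by 0.77 ± 0.12, a call lost without control diet 2 (adjusted p = 0.12) and a change of 0.01 once the fenestrated-like cells were left out. Ttr, the abundant transthyretin transcript of the choroid plexus, read 1.89 and 82.1 CPM in the endothelial sums of control diet 1 and 2 and 0 in both PLX5622 libraries (adjusted p = 0.767). Plvap lies on chromosome 8 from 71497765 to 71511752.

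Angpt2, the Tie2 ligand angiopoietin-2, rose from 7.31 ± 0.970 to 34.0 ± 10.98 CPM (log2 fold change 2.28 ± 0.23), and Dll4, a Notch ligand, rose by 0.50 ± 0.09. Of 16 tested genes of angiogenesis and tip cells, 2 rose, 1 fell (Esm1, also a fenestrated marker) and 13 did not pass, with 5 and 1 when adjusted over the list alone (higher by camera, adjusted p = 0.266 with an estimated correlation). Their mean log2 fold change was -0.14 as fitted and 0.09 with Esm1 at its bound, while the median was 0.10 both ways. Without control diet 2 none passed (adjusted p of 0.169 for Angpt2 and 0.0845 for Dll4), without control diet 1 Angpt2 did not (adjusted p = 0.0815), and without PLX5622 diet 1 the count was 4 and 1. In the Wnt pathway, which maintains the barrier, 0 of 19 tested rose, 1 fell and 18 did not pass, with 1 and 2 when adjusted over the list alone. That gene, the Wnt deacylase Notum, fell by 0.43 ± 0.09 with both PLX5622 libraries below both controls, and lost its call without any 1 of the 4 libraries (adjusted p between 0.0719 and 0.193). Without PLX5622 diet 1 another Wnt gene was higher. Of 10 Notch pathway genes 0 passed in the 3 tools, with 2, 3 and 2 at an unadjusted p under 0.05 and 1 higher when adjusted over the list alone. Of 10 TGF-beta and BMP targets 0 passed in edgeR and 1 was higher in DESeq2 and in limma-voom, with 2 at an unadjusted p under 0.05 in each tool and 1 higher when adjusted over the list alone (higher by camera, adjusted p = 0.372 with an estimated correlation).

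Ankrd37, a hypoxia-inducible gene, rose from 34.8 ± 5.95 to 96.8 ± 1.17 CPM (1.45 ± 0.11 on the log2 scale). Of 15 tested genes of hypoxia and glycolysis, 3 rose (Ankrd37, Bnip3 and Ldha), 0 fell and 12 did not pass, with 6 when adjusted over the list alone (adjusted p = 0.266 with an estimated correlation). The number was 1 without control diet 1, with an adjusted p of 0.115 for Bnip3 and 0.198 for Ldha, and Ldha also missed the threshold without PLX5622 diet 1 (0.174) and in DESeq2 (0.437). Of 11 heat shock genes, 3 rose (the chaperones Hspe1, Dnaja1 and Hspa1b), 0 fell and 8 did not pass, with 6 when adjusted over the list alone (adjusted p = 0.372 with an estimated correlation). The heat shock number was 0 without control diet 1, without control diet 2 it was 1, and without PLX5622 diet 2 it was 6. The adjusted p without control diet 1 was 0.0802 for Hspe1, 0.159 for Dnaja1 and 0.2 for Hspa1b, without control diet 2 it was 0.082 for Dnaja1 and 0.109 for Hspa1b, and without PLX5622 diet 1 it was 0.465 and 0.323 for these. Hspa1b also did not pass in DESeq2 (adjusted p = 0.0569). Of 10 glucocorticoid targets, 1 rose (Sult1a1), 1 fell (Pdk4) and 8 did not pass, with 2 and 3 when adjusted over the list alone. Their mean was 0.02 and their median -0.20, with a lower direction in camera that did not pass (adjusted p = 0.442). The counts were 0 and 0 without control diet 1 (adjusted p of 0.0818 for Sult1a1 and 0.137 for Pdk4), without control diet 2 they were 1 and 0 (Pdk4 0.119), and without PLX5622 diet 2 they were 2 and 0 (Pdk4 0.0703). In DESeq2 Pdk4 did not pass (adjusted p = 0.146). Cebpd, a transcription factor of the acute phase response, rose by 1.00 ± 0.10 on the log2 scale (98.3 ± 11.3 to 198 ± 6.35 CPM). P4ha1, a collagen prolyl hydroxylase, rose by 1.05 ± 0.17 and did not pass without control diet 1 (adjusted p = 0.161) or control diet 2 (adjusted p = 0.137).

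Nr1d1, the circadian repressor REV-ERB alpha, fell from 112 ± 15.5 to 69.4 ± 8.38 CPM (-0.69 ± 0.11), its paralog Nr1d2 fell by 0.63 ± 0.11, and Ciart, a circadian co-repressor, by 0.61 ± 0.09. The adjusted p of Nr1d1 was 0.0697 and that of Nr1d2 0.0719 without control diet 1. Of 10 other clock genes, chosen after these values were seen, 0 passed in edgeR, DESeq2 and limma-voom, with 2, 0 and 1 at an unadjusted p under 0.05, and Hlf (0.23 ± 0.13) and Per2 (0.43 ± 0.37) lay on the higher side. Per1, a clock gene outside these 10 that the glucocorticoid list holds, read -0.33 ± 0.09 with both PLX5622 libraries below both controls (adjusted p = 0.119). The other named genes that fell were Lmntd1 (-1.02 ± 0.12), the anion transporter family gene Slc26a10 (-0.82 ± 0.10), the cold-inducible RNA-binding protein gene Cirbp (-0.75 ± 0.11), Prrt4 (-0.70 ± 0.11), the costimulatory receptor gene Cd40 (-0.68 ± 0.11) and Cthrc1 (-0.61 ± 0.11). Cirbp (0.0638), Prrt4 (0.0823), Cd40 (0.0969) and Cthrc1 (0.123) missed the adjusted threshold without control diet 2, and Cthrc1 missed it without PLX5622 diet 2 (0.0679).

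In the remaining lists 0 members passed in edgeR, DESeq2 and limma-voom. At an unadjusted p under 0.05 these tools found 1, 1 and 1 of 12 basement membrane genes, 1, 1 and 0 of 13 cell cycle genes, 1, 4 and 1 of 15 immediate early and dissociation genes, 2, 1 and 2 of 8 shear stress genes, 0 in each tool of 13 mitochondrially encoded transcripts, 0 in each of 10 NRF2 and metallothionein genes, 4, 2 and 3 of 14 genes of the unfolded protein and integrated stress response, and 3, 2 and 3 of 9 xenobiotic metabolism genes. Adjusted over the list alone, 1 shear stress gene was higher and 1 lower, 1 unfolded protein gene was higher and 1 xenobiotic gene was lower, with 0 in the others. One shear stress gene was lower without PLX5622 diet 1. Camera called the immediate early genes lower (adjusted p = 0.748 with an estimated correlation) and the mitochondrial and unfolded protein lists higher (adjusted p = 0.748 with an estimated correlation for both). Directions differed in sign for basement membrane (mean 0.02, median -0.01, camera higher), shear stress (mean 0.00, median -0.09, camera lower) and NRF2 genes (mean 0.01, median 0.02, camera lower). Of the receptors related to CSF1R, 3 had enough counts and 0 passed in any tool, namely Kit (0.77 ± 0.35), Pdgfra (-0.79 ± 0.50) and Pdgfrb (-0.38 ± 0.34), with 1, 0 and 1 at an unadjusted p under 0.05 in edgeR, DESeq2 and limma-voom and 0 when adjusted over the list alone. In all, camera called 12 of 27 lists higher and 3 lower, none held with an estimated correlation, and fry called 3 (cholesterol synthesis, sterol uptake and inflammatory signalling, adjusted p = 0.0358 for each).

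**Figure D3:**
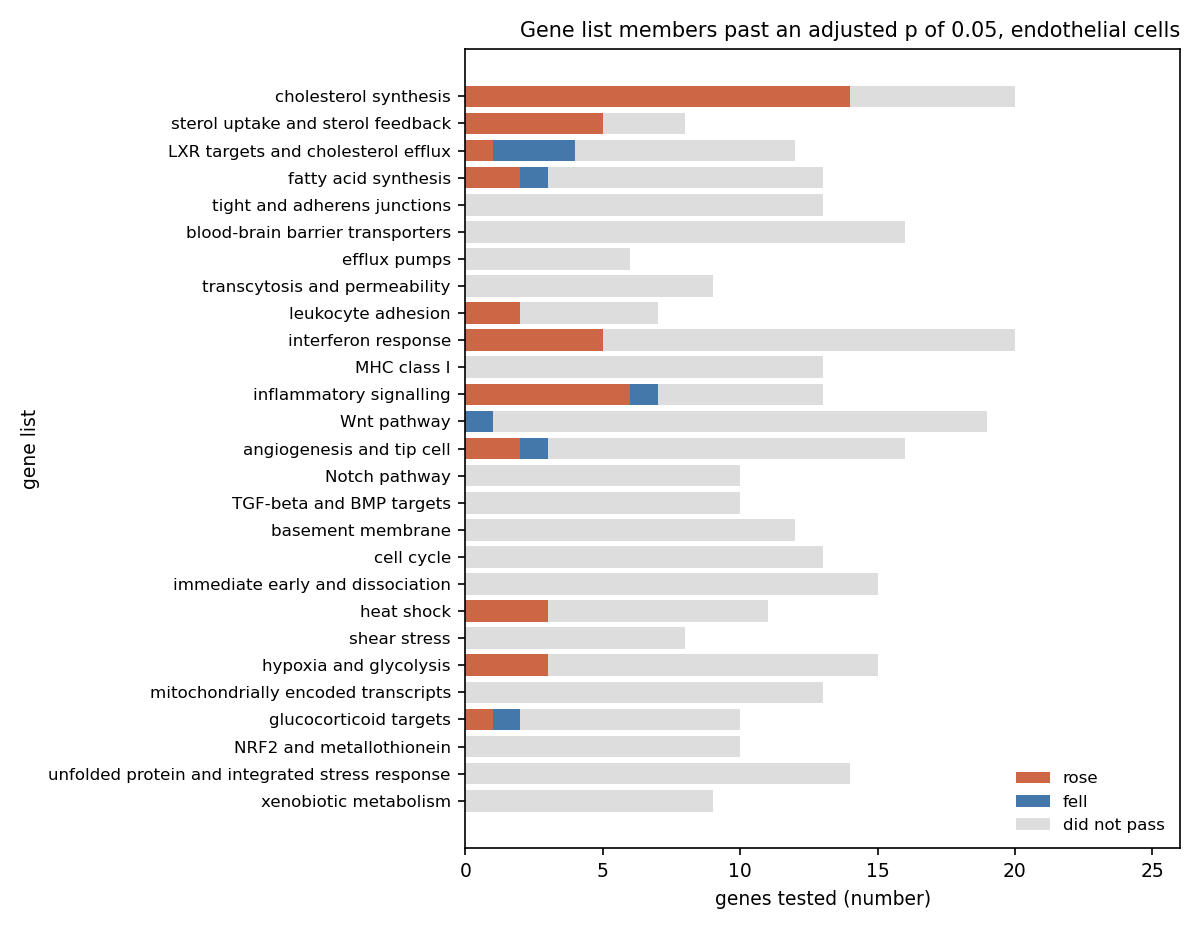
Number of tested members of each fixed gene list that rose, fell or did not pass an adjusted p of 0.05 in edgeR, endothelial cells of 2 libraries per diet. Cholesterol synthesis has 14 of 20 members higher, and the junction, transporter and efflux lists have 0.

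Markers of other cell types were measured in the same endothelial sums. The haemoglobin genes Hba-a2, Hbb-bt and Hba-a1 rose by 1.09, 1.35 and 0.90 on the log2 scale. Of the tested markers of pericytes (8, median log2 fold change 0.34), smooth muscle (6, median 0.53), astrocytes (4, median -0.07) and neurons (5, median 0.89), 0 passed in edgeR, with 3, 3, 0 and 2 at an unadjusted p under 0.05. DESeq2 and limma-voom each passed 1 pericyte marker as higher and 0 of the others, with 1, 0, 0 and 0 and with 3, 3, 0 and 2 at an unadjusted p under 0.05. Along the vessel tree, the venous markers Lcn2, Il1r1 and Ackr1 were higher and the arterial markers Alpl (-0.52 ± 0.11) and Bmx (-0.51 ± 0.11) lower. Lcn2, Il1r1 and Ackr1 thus stand both among the inflammatory and adhesion genes above and among the venous markers.

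The next comparison asked whether the diet effect was seen along the vascular tree. Arterial-like, capillary-like and venous-like cells all had higher Insig1 on PLX5622, by 1.34 ± 0.16, 1.58 ± 0.13 and 1.62 ± 0.15 on the log2 scale. Msmo1 (1.33 ± 0.16, 1.55 ± 0.15 and 1.68 ± 0.15) and Idi1 (1.21 ± 0.16, 1.46 ± 0.13 and 1.60 ± 0.16) rose in each, and Abca1 fell in each (-0.74 ± 0.16, -1.40 ± 0.16 and -1.39 ± 0.17). Cholesterol synthesis had 10 of 19, 10 of 20 and 10 of 20 tested members higher, with medians of 0.96, 0.81 and 0.76. Arterial-like cells had 46 genes higher and 19 lower of 10582, capillary-like cells 69 and 23 of 11314, and venous-like cells 116 and 32 of 10490. Without normalization factors the capillary-like counts were 64 and 48.

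Of the genes changed in all endothelial cells, 134 of 138 tested in arterial-like cells had the same sign there and 45 passed. In capillary-like cells 135 of 138 had the same sign and 64 passed, and in venous-like cells 135 of 136 and 70. These comparisons share libraries and cells, so such agreement is high by construction. In arterial-like cells Cyp51 (1.68 ± 0.19) and Ccn3, a matricellular protein (1.34 ± 0.18), were also higher, and Nr1d2 (-0.80 ± 0.16), Cirbp (-0.76 ± 0.13), Nr1d1 (-0.75 ± 0.13) and Ciart (-0.74 ± 0.15) lower. In capillary-like cells Angpt2 was higher (1.99 ± 0.20), and Abcg1 (-1.39 ± 0.22), Lmntd1 (-1.09 ± 0.16), Prrt4 (-0.88 ± 0.15) and Cthrc1 (-0.83 ± 0.16) were lower. In venous-like cells Ptgs2 (2.11 ± 0.13) and Ch25h (2.03 ± 0.20) were higher, and Abcg1 (-1.75 ± 0.21), Mylip (-1.41 ± 0.21), the cell cycle inhibitor gene Cdkn2b (-1.03 ± 0.15) and Ramp3, a co-receptor of the adrenomedullin receptor (-0.93 ± 0.20), were lower. Lcn2, Ackr1 and Il1r1 were among the markers that named the venous clusters and are not results there. Ptgs2 and Ch25h were not among those markers. They led a first-stage cluster of 453 venous cells, at a step that named no subtypes. Ch25h was kept out of the genes of the second step, while Ptgs2 was not.

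The number of changed genes in a subtype moved with the libraries used. Without control diet 1 or 2 arterial-like cells gave 87 and 49 or 83 and 45 genes, and without PLX5622 diet 2 they gave 18 and 10. Without PLX5622 diet 1 they gave 46 and 13. Capillary-like cells gave 35 and 15 without control diet 1 and 43 and 10 without control diet 2. Venous-like cells gave 176 and 62 without control diet 1, 137 and 50 without control diet 2, 98 and 19 without PLX5622 diet 1, and 78 and 20 without PLX5622 diet 2. The capillary-like class joined 2 clusters, the first with 332, 982, 992 and 799 cells in control diet 1 and 2 and PLX5622 diet 1 and 2, and the second with 184, 494, 554 and 749. A cluster led by Tcim, Rgcc and Fam110a matched no subtype and held 26.6%, 28.2%, 27.0% and 18.0% of the clustered endothelial cells in the same order. It stayed in the endothelial sums but entered no subtype sum. Its naming thresholds were set after the data were seen. Clusters mixed with pericyte or erythroid genes were left out of the endothelial sums and held 0.650%, 0.726%, 1.56% and 1.14% of kept cells.

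**Figure D4:**
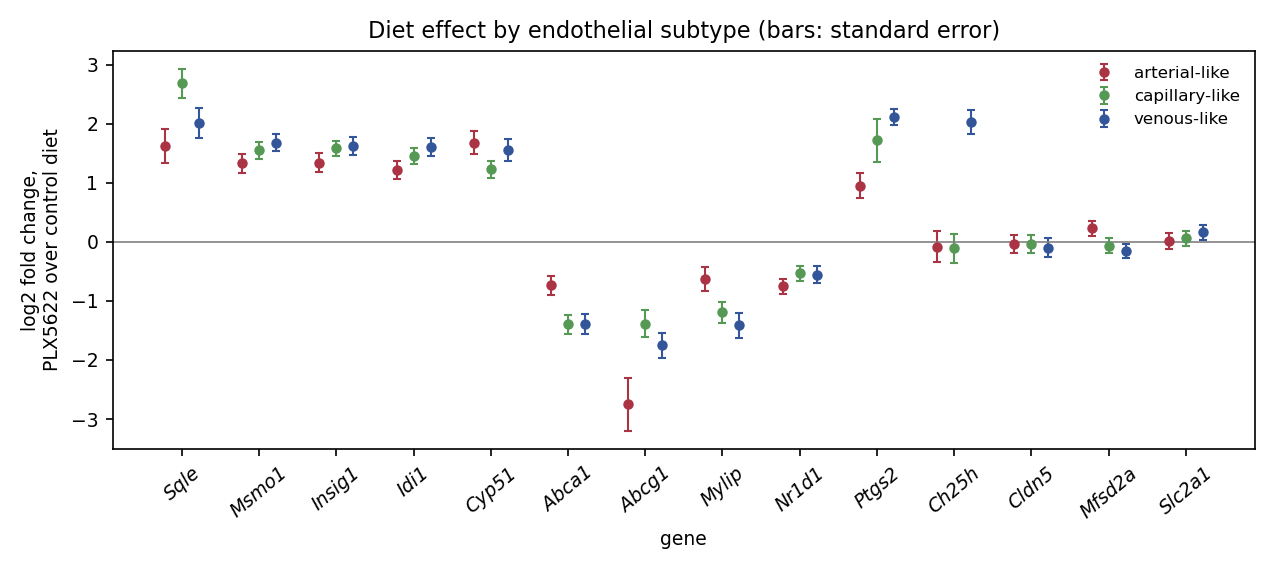
Log2 fold change of PLX5622 over control diet for 14 genes in arterial-like, capillary-like and venous-like sums (points; bars, standard error from edgeR; 2 libraries per diet). Insig1 is higher in all 3 subtypes (1.34, 1.58 and 1.62), Ch25h is at 2.03 in venous-like cells and -0.11 in capillary-like cells, and Cldn5 is near 0 throughout.

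Differences in the diet effect between subtypes were tested as interactions over 12 sums. Against capillary-like cells, 12 genes responded more positively and 21 more negatively in arterial-like cells, and 23 and 25 did so in venous-like cells, of 11370 tested. These counts include markers that named the subtypes and are not results here. Among them are Vcam1, Mfsd2a and Rgcc in the arterial counts and Rgcc and Slc38a5 in the venous counts. Abca1 fell less in arterial-like than in capillary-like cells (difference 0.71 ± 0.18, adjusted p = 0.039). Cxcl1 rose by 1.31 ± 0.19 in capillary-like cells and read 0.39 ± 0.16 in arterial-like cells, where it did not pass (adjusted p = 0.463), a difference of -0.88 ± 0.20 (adjusted p = 0.0185). In venous-like cells Ch25h responded more positively by 2.17 ± 0.26, Fth1, the ferritin heavy chain, by 0.70 ± 0.05 and Cebpd by 0.54 ± 0.12. Venous markers that rose on PLX5622 helped to form and name the venous-like class. Cells that responded to the diet may thus have been placed in it, which could enlarge these differences. The interaction for Insig1 did not pass in arterial-like cells (-0.18 ± 0.17, adjusted p = 0.995). Without PLX5622 diet 2 the arterial counts were 2 and 7 and the venous counts 11 and 8. Leaving out control diet 2, the arterial counts were 13 and 14 and the venous counts 11 and 3. Another seed for the clustering, tried after the data were seen, gave 3 and 5 arterial and 12 and 10 venous genes.

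Other cells that passed the sort were few. Pericyte-like cells on PLX5622 had more Mt1, a metallothionein (1.11 ± 0.17), and more Cebpb, an inflammatory transcription factor (1.21 ± 0.23), 2 genes higher and 0 lower of 6626. Without control diet 1 the counts were 0 and 3, without PLX5622 diet 1 they were 16 and 3, and without PLX5622 diet 2 they were 21 and 5. DESeq2 gave 1 and 0 and limma-voom 3 and 3, with 424 genes at an unadjusted p under 0.05 in edgeR, 71 in DESeq2 and 491 in limma-voom. Smooth muscle-like cells had 0 genes higher and 0 lower of 6288 in edgeR, DESeq2 and limma-voom, with 316, 46 and 343 genes at an unadjusted p under 0.05. The smooth muscle genes of smallest p were Tppp3 (-1.44 ± 0.28, adjusted p = 0.262), Edn1 (-2.66 ± 0.54, adjusted p = 0.271) and Gm26802 (1.35 ± 0.30, adjusted p = 0.287). Leaving out control diet 1 gave 42 and 185 smooth muscle genes, and leaving out control diet 2 gave 2 and 5. With 36, 70, 60 and 60 such cells per library, a 2-fold change was recovered for 32.8% of genes in simulated data.

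Erythroid-like cells, led by haemoglobin genes, had 19 genes higher and 1 lower of 7779. The higher ones included Msmo1 (2.13 ± 0.37), Insig1 (1.98 ± 0.35), Cyp51 (1.88 ± 0.40) and Idi1 (1.83 ± 0.39), and the lower one was Crip1 (-0.85 ± 0.18). These 384 cells had a median of 11186 UMIs against 5114 in endothelial-like cells, and all of them held UMIs of Cldn5, at 4493 CPM against 7510 CPM in endothelial-like cells. Each thus held RNA of an endothelial gene, so these sterol changes cannot be told apart from those of endothelial cells. Pericyte-like cells also carried Cldn5, at 4802 CPM with UMIs in 69.4% of cells, and smooth muscle-like cells at 533 CPM. The pericyte-like sums thus include endothelial RNA, and whether Mt1 and Cebpb rose in pericytes themselves was not tested. The erythroid counts were 0 and 1 without PLX5622 diet 1, 10 and 1 without PLX5622 diet 2, 15 and 2 without control diet 2, and 74 and 21 without control diet 1. DESeq2 gave 4 and 0 genes and limma-voom 59 and 13. With the replicate block, edgeR gave 0 and 0 erythroid genes.

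Shares of cell classes reflect what the CD31 sort let through. Endothelial-like cells were 89.2% ± 0.235 (SD, n = 2) of kept cells on control diet and 87.3% ± 0.856 on PLX5622. Pericyte-like cells were 1.81% ± 0.0240 and 2.06% ± 0.01001, smooth muscle-like cells 1.70% ± 0.605 and 1.57% ± 0.0919, erythroid-like cells 1.83% ± 0.830 and 3.01% ± 0.0652, and astrocyte-like cells 0.777% ± 0.0713 and 0.412% ± 0.227. Clusters that matched no class held 3.66%, 3.70%, 3.59% and 4.69% of cells in control diet 1 and 2 and PLX5622 diet 1 and 2. With 2 libraries per diet an exact two-sided permutation test cannot give a p below 0.333, and no test of shares was run. The pericyte difference of 0.25 points was -0.04 when cells needed 2000 UMIs.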

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

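The interaction tests were planned, and both tests of explanations in this part were chosen only after the results were seen, with the rule for reading them revised after their values were known so that it takes in their spread. The 10 genes below had the smallest p of 33 arterial and 48 venous genes, 5 of each, whose diet effect differed from that in capillary-like cells in a test of the difference itself, over 12 sums of only 4 libraries. Against capillary-like cells, venous-like cells responded more positively in Fth1, the ferritin heavy chain (0.70 ± 0.05 on the log2 scale), in Ch25h (2.17 ± 0.26), in Edn1, the vasoconstrictor endothelin (0.51 ± 0.07), in Tmem252 (0.61 ± 0.08) and in Cp, the ferroxidase ceruloplasmin (0.78 ± 0.10). Fth1 rose by 0.90 ± 0.14 in venous-like cells and read 0.21 ± 0.14 in capillary-like cells, and Cp rose in both, by 1.38 ± 0.12 and 0.61 ± 0.11. Tmem252 rose by 0.66 ± 0.11 in venous-like cells, while Edn1 did not pass in either subtype (0.39 ± 0.11 and -0.10 ± 0.11). Inflammatory genes were not kept out of the clustering, and some venous markers rose on PLX5622. The test therefore cannot tell a larger venous response from responding cells being placed in the venous-like class. Fth1 lies on chromosome 19 from 9980598 to 9985098 and Ch25h on chromosome 19 from 34473778 to 34475164 (GRCm38).

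In arterial-like cells the effect was more negative than in capillary-like cells for Depp1, a FOXO target (-0.83 ± 0.10), and for Mt1 (-0.46 ± 0.06). Rgcc came out at -0.42 ± 0.06 but was among the markers that named the capillary clusters, so this value is not a result. The effect was more positive for Rad54b, a DNA repair helicase (0.75 ± 0.11), and for Crip1, a LIM domain protein (0.38 ± 0.06). Depp1 did not pass in either subtype on its own (0.32 ± 0.12 and 1.17 ± 0.26), and neither did Mt1 (-0.23 ± 0.13 and 0.25 ± 0.12) or Rad54b (0.19 ± 0.12 and -0.55 ± 0.14). Crip1 fell by 0.62 ± 0.14 in capillary-like cells. With another clustering seed, tried after the data were seen, the differences for Mt1 (-0.19, adjusted p = 0.727), Rgcc (-0.21, adjusted p = 0.654) and Edn1 (0.092, adjusted p = 0.911) did not pass. At clustering resolution 1.0 those for Edn1 (0.25, adjusted p = 0.486), Cp (0.39, adjusted p = 0.257) and Crip1 (0.29, adjusted p = 0.064) did not, and without PLX5622 diet 2 that for Crip1 did not (adjusted p = 0.0508) and that for Depp1 was -0.52.

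Lcn2, Ackr1, Sele, Ptgs2, Il1r1, Ch25h and Cxcl1 were weighed as a pattern because they rose in all endothelial cells, although Lcn2, Ackr1 and Il1r1 also named the venous clusters and Ptgs2 and Ch25h led a cluster of 453 venous cells. Free RNA is argued against, as on PLX5622 it supplied a median of 0.505% and at most 1.497% of the rise of these 7 genes in the endothelial sums. A larger number of cells from large veins in the PLX5622 libraries stays open. Of the 7 genes, 4 were tested in arterial-like cells (Ptgs2, Cxcl1, Ch25h and Il1r1). These 4 had a median of 0.19 there with a spread of 0.24 (SD over the genes divided by the root of their number), against 0.81 in all endothelial cells. Of them Ptgs2 alone passed in arterial-like cells (0.95 ± 0.21). That median cannot decide the question, because Il1r1 named the venous clusters and cells high in it would not be named arterial-like. In capillary-like cells Ptgs2 (1.72 ± 0.36) and Cxcl1 (1.31 ± 0.19) passed as higher and Ch25h (-0.11 ± 0.25) did not pass. Lcn2 (3.15 ± 0.37) passed there and Il1r1 (0.60 ± 0.24) did not, but both named the venous clusters and are not results within subtypes. These values cannot decide the question, because inflammatory genes were not kept out of the clustering. Ptgs2 was also low in capillary-like cells (1.56 and 1.89 CPM on control diet, 5.64 and 6.25 CPM on PLX5622). Venous-like cells numbered 269 and 992 of 1513 and 4905 endothelial-like cells on control diet and 465 and 456 of 3504 and 3181 on PLX5622. These sizes decide nothing because genes naming these clusters differ between diets. A response of the cells to the diet, through the loss of microglia or through the compound itself, also stays open, and this design cannot separate those routes.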

How the results depend on the processing

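Among the tests here, the removal of high doublet scores, the removal of fenestrated-like cells, another clustering seed, and the alternatives for other cell classes were chosen after seeing the data; the rest were planned. With 2 libraries per diet, leaving 1 out assumes that the lone library varies like the other diet's pair. Of the 52 named genes that passed, 34 kept their call without control diet 1, 30 of 51 without control diet 2, 48 without PLX5622 diet 1 and 45 without PLX5622 diet 2. DESeq2 kept 49, equal weight to the subtypes 46 of 51, and thinning to the smallest library 49 of 51. Over all named genes and alternatives, 2974 results held their direction and side of the threshold, 64 were weaker, 47 stronger and 18 reversed, 16 of those with no call in either fit. For gene lists the numbers were 319, 38, 5 and 16. Except where shown by fewer genes or cells entering a test, the cause of each change was not tested.

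Leaving out 1 library gave 45 to 157 higher and 19 to 67 lower genes in endothelial cells, 18 to 87 and 10 to 49 in arterial-like, 35 to 82 and 10 to 26 in capillary-like, and 78 to 176 and 19 to 62 in venous-like cells. It gave 0 to 42 and 0 to 185 in smooth muscle-like, 0 to 21 and 0 to 5 in pericyte-like, and 0 to 74 and 1 to 21 in erythroid-like cells. For the interaction it gave 2 to 13 and 7 to 22 arterial and 11 to 22 and 3 to 30 venous genes. Camera called 10 to 12 lists higher and 1 to 4 lower.

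With the replicate block, endothelial cells had 212 higher and 115 lower genes, arterial-like cells 93 and 46, capillary-like cells 162 and 73, venous-like cells 182 and 66, smooth muscle-like cells 3 and 37, pericyte-like cells 14 and 6, and erythroid-like cells 0 and 0. The deviations of libraries with the same replicate number correlated at 0.071, and nothing in the labels pairs them. The block kept 50 of the 52 named calls.

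In endothelial cells a mean CPM of at least 20, which tests fewer genes, gave 62 higher and 25 lower, no low-count filter gave 77 lower, equal weight to the subtypes 26 lower, and leaving out fenestrated-like cells 33 lower. Arterial-like cells had 17 higher and 4 lower genes with at least 500 UMIs and 300 genes per cell, and 12 lower at clustering resolution 1.0. Capillary-like cells had 112 higher and 57 lower genes with at least 2000 UMIs per cell, and 48 lower without normalization factors. In pericyte-like cells DESeq2 gave 1 higher and limma-voom 3 lower. In erythroid-like cells DESeq2 gave 4 higher and 0 lower and limma-voom 59 and 13. The interaction at resolution 1.0 had 6 higher arterial and 15 lower venous genes, and with another seed 3 higher and 5 lower arterial and 12 higher and 10 lower venous genes. Camera with an estimated correlation called 0 lists higher and 0 lower, and fry 3 and 0. The pericyte share difference of 0.25 points became -0.038 with at least 2000 UMIs, 0.317 with at least 500 UMIs and 300 genes, 0.155 with called doublets kept and 0.140 at resolution 1.0.

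Camera's direction reversed for 9 lists when a library was left out, and each adjusted p is given as the range over the 4 such fits. For MHC class I it ranged from 2.0e-08 (higher, without control diet 1) to 0.765, and was 0.0125 with a lower direction without control diet 2. The other ranges were 0.264 to 0.995 for junctions (reversed without PLX5622 diet 2), 0.062 to 0.942 for transporters (without PLX5622 diet 1, 0.461), 0.0372 to 0.760 for efflux pumps (without control diet 2), 0.00935 to 0.995 for the Wnt pathway (without PLX5622 diet 2), 0.0769 to 0.947 for basement membrane and 0.232 to 0.963 for cell cycle (both without control diet 2 or PLX5622 diet 1, at 0.275 and 0.905 in the fits not at the range's end), 0.460 to 0.947 for NRF2 genes (the same libraries, 0.641), and 0.546 to 0.844 for xenobiotic metabolism (without control diet 1 or PLX5622 diet 1, 0.788). Other reversals were transcytosis with fenestrated-like cells left out (0.945), basement membrane without normalization factors (0.922) and NRF2 genes in fry (0.990).

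Among genes that reversed, Plpp3 had a log2 fold change of 0.15 with equal weight to the subtypes and 0.0067 with fenestrated-like cells left out. With 1 library left out, the values ranged from -0.034 to 0.33 for Psmb9, from -0.50 to 0.057 for Pdgfrb, from -0.012 to 0.22 for Id2, from -0.041 to 0.26 for Lrp8, from -0.088 to 0.29 for Mfsd2a and from -0.027 to 0.19 for Ctnnd1. The ranges were -0.20 to 0.018 for Cavin1, -0.14 to 0.0061 for Tjp1, -0.11 to 0.094 for Abcb1a and -0.15 to 0.14 for Cldn5. Srxn1 read 0.0035 after thinning, Slc7a11 -0.21 and Abcb1a 0.0036 with at most 5% mitochondrial UMIs, and Cldn5 0.016 in limma-voom. In simulated data at the depth and spread of each comparison, a 1.5-fold change was recovered for 61.2% of genes in endothelial, 34.3% in venous-like and 3.23% in smooth muscle-like cells.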

Other observations

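All 3 tests of explanations in this part were chosen only after the results were seen, and the rule for reading them was revised after their values were known so that it takes in their spread. Spread is the SD over genes divided by the root of their number, combined over both sets for a difference. It takes genes as independent and is not a spread between libraries. The first pattern is the rise of sterol synthesis genes in endothelial cells. A changed mix of subtypes is argued against. The median log2 fold change of the cholesterol synthesis genes was 0.82 with equal weight to the 3 subtypes. It was 0.86 as reported, and the spread of 0.11 that the rule used was taken from that reported fit. The endothelial cluster that matched no subtype did not enter the equal-weight sums. A rise of astrocyte RNA in the endothelial sums was not seen in the 4 tested astrocyte markers, whose median was -0.072 with a spread of 0.15. Aldoc, Slc1a2 and Slc1a3 among them were low (means of 0.97, 1.42 and 2.38 CPM on control diet), which limits this test. Marker medians were higher for neurons (0.89), smooth muscle (0.53) and erythroid cells (1.07) and lower for oligodendrocytes (-0.10) and their precursors (-0.62). RNA of these cells was not tested as a source. One hypothesis left is that endothelial cells sensed less sterol on PLX5622, which would be consistent with higher Insig1 (1.46) and lower Abca1 (-1.17), but no sterol was measured, and a direct action of the compound on endothelial cells or other cells was not tested.

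The second pattern is the fall of Nr1d1, Nr1d2 and Ciart on PLX5622. Brains taken at another time of day remain a candidate explanation that cannot be excluded. Clock genes that run against Nr1d1 lay 0.31 above those that run with it (spread 0.14), with medians of 0.05 over 4 genes and -0.26 over 6, and 0.31 above (spread 0.13) with Per1 (-0.33 ± 0.09) added to the 6. In edgeR, DESeq2 and limma-voom 0 of these 10 genes passed, with 2, 0 and 1 at an unadjusted p under 0.05, and Hlf (0.23 ± 0.13) and Per2 (0.43 ± 0.37), which run with Nr1d1, went the other way. The labels used here give no time of collection.

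Among genes near 0 counts, Grem1, a BMP antagonist, had 3 UMIs in control endothelial cells and 29 on PLX5622, a ratio of 10.8 with a counting interval from 3.34 to 55.3. A cluster outside the named classes was led by the platelet genes Pf4 and Ppbp and held 172 cells. A group of 8 cells that clustered apart was led by microglial genes, but Csf1r was detected in 37.5% and the endothelial gene Cldn5 in 75% of them, and 0 kept cells on PLX5622 held 3 or more of the 12 microglial markers.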
